A study of Mus musculus with 3 samples.

How the data were processed

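The data were total RNA sequencing of the chromatin fraction of mouse bone-marrow-derived macrophages after ribosomal RNA depletion, in 1 group of 3 biological replicates with a fragment size range of 250 to 400 in the labels. The labels give 1 donor identifier for the 3 libraries and do not say whether they came from separate animals, so the spread between them may be partly technical. Each library had 3 deposited tables, on mm10 with GENCODE release M21 according to the README files deposited with them. The tools and their versions were not given in the sources used here. The gene table and the alignment-based transcript table give expected counts and TPM that the authors estimated from alignments to the transcriptome, per the file headers and README files. The read-based transcript table gives estimated counts and TPM that the authors derived directly from the reads, as deposited. TPM divides a count by the effective length of the transcript and scales each library to the same total, so a few abundant or very short RNAs lower the TPM of all others. A feature with an effective length of 0 can be listed at 0 TPM despite its counts, as Snord22 was in replicates 2 and 3. Whether strand was used in counting is not given in the sources used here, so reads of overlapping genes on opposite strands, and of near-identical gene copies such as histones, Gbp or H2 genes, may be split between them with error.

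The expected counts totalled 14609979, 17423948 and 24162551 in replicates 1, 2 and 3, with median counts of 150, 181 and 239 per detected gene. The read-based tables totalled 23135627, 30418666 and 40940944 estimated counts. Rows that belong to no annotated gene (phiX174, 96 ERCC spike-in sequences and 26248 features with a number as identifier) held 1.24, 0.482 and 0.228% of the counts and were left out of gene tests. The ERCC sequences had 0 counts in each library, which allows a share of at most 2.05e-05% in replicate 1. Confidence intervals of shares are exact binomial 95% intervals. PCR reads without molecular identifiers are not independent molecules, so intervals and limits cover counting error only.

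All 55536 annotated genes had a row in the gene table, with coordinates from GENCODE M21 (mm10, 1-based). A gene was detected at a mean expected count of at least 10. Levels used log2(TPM + 1), which understates differences between low genes. TPM values are from the alignment-based gene table unless the read-based table is named, and values and order of genes differed between them. The design, the 23 gene lists, a first set of alternatives and the rule for named genes were fixed before the data were examined, and some alternatives and contrasts were added later. That rule took the 5 highest detected and 2 lowest members of the immediate early, early inflammatory and late inflammatory lists, the 3 highest and 1 lowest of each other list, the 10 genes with the highest TPM, and the 10 with the largest SD among those with a mean count of at least 100. Some genes that the rule takes are not reported here. Of 359 listed symbols, 357 had a gene, and a symbol with several identifiers took the lowest.

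List levels were set against 10000 random lists of protein-coding genes of the same size. Spread (SD over libraries) and deviation (a library minus the mean of the other two) were set against 10000 random lists of detected genes matched in 20 expression bins, for lists with at least 3 detected members. These percentiles describe these libraries and are not p-values. List contrasts used 2-sided permutation of genes (100000 draws), with Benjamini-Hochberg adjustment. For list levels the permutation used each gene's mean over the libraries, whereas the differences given are means of the differences in each library. The retained intron share was the percent of a gene's TPM in transcripts of that annotated type, for genes with a protein-coding transcript and a mean of at least 1 TPM. Transcript shares depend on how reads common to several isoforms were divided. Expected counts were rounded to whole numbers for edgeR 4.0.16 (TMM scaling and dispersion with an intercept only) and DESeq2 1.42.0 under R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and BLAST 2.17.0 for gene copies (identity of at least 95% over at least 80% of the gene).

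The steps were tested on simulated counts. Biological coefficients of variation of 0.1, 0.2 and 0.4 simulated for 15879 genes came back as 0.0997, 0.200 and 0.398. With 200 of 15873 genes raised in replicate 1, in 10 lists, all 10 lists passed percentile 97.5 at folds of 1.5, 2 and 4, and 1 of 10 passed at a fold of 1. Of 200 permutation tests on random lists, 5.50% gave p below 0.05. Alternatives covered the quantification, pseudocount, filters, scaling, background lists and leaving out each replicate. With 1 group, no test between conditions, block or split of samples applied.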

Results

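RNA bound to chromatin was sequenced from mouse bone-marrow-derived macrophages, primary immune cells grown from bone marrow of the C57BL/6J strain. The cells had received Lipid A, the part of bacterial lipopolysaccharide that activates the receptor TLR4, at 100 ng/ml for 12 h. After 12 h without it they were stimulated again at 100 ng/ml for 15 min. The series holds 1 group of 3 libraries, which the labels number as biological replicates 1, 2 and 3, and no untreated or singly stimulated group was analysed here. The libraries began from 1000, 250 and 500 ng of RNA and gave 14609979, 17423948 and 24162551 expected counts in replicates 1, 2 and 3. With 1 group, the design allowed a description of which gene groups carried chromatin RNA, of contrasts between gene groups within the cells, and of how far the replicates lay apart.

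Interferon-stimulated genes had the highest median level of the protein-coding gene lists examined. The interferon list had a median of 7.40 ± 0.47 (log2(TPM + 1), SD, n = 3), where TPM is the length-scaled share of transcripts in a library, against 4.90 ± 0.25 for early inflammatory genes, 4.34 ± 0.24 for immediate early genes and 1.32 ± 0.46 for late inflammatory genes. Mx1 (ENSMUSG00000000386.15), a GTPase gene on chromosome 16 from 97447035 to 97462907 (mm10), had the highest mean of all protein-coding genes at 2148 ± 703 TPM. Stat2, which carries the interferon signal to the nucleus (chromosome 10, 128270559 to 128292849), reached 698 ± 110 TPM, and the antiviral gene Rsad2 reached 672 ± 277 TPM. The chemokine gene Cxcl9 was the lowest of the 24 interferon members at 0.190 ± 0.234 TPM, but not in the read-based table, where it had 1.27 ± 0.11 TPM. The interferon median exceeded all 10000 random lists of protein-coding genes of the same size. The housekeeping and ribosomal protein medians did so too, and the random lists drew on detected and undetected genes alike. This percentile thus does not set the interferon list apart from other expressed genes.

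Among the 30 early inflammatory genes, 28 had a mean of at least 1 TPM. The highest were Tnfaip2 at 269 ± 40.4 TPM (chromosome 12, 111442469 to 111455018), Sod2, the mitochondrial superoxide dismutase, at 186 ± 75.7, Birc3 at 128 ± 29.4, the NF-κB inhibitor gene Nfkbia at 111 ± 30.9 and Pim1 at 104 ± 21.2 TPM. The read-based table gave 380 ± 49.1 for Tnfaip2, 244 ± 36.5 for Birc3, 200 ± 46.6 for Nfkbia, 191 ± 64.7 for Sod2 and 187 ± 27.8 TPM for Pim1. The chemokine gene Cxcl3 (0.0600 ± 0.0529 TPM) and Phlda1 (0.627 ± 0.579 TPM) were the lowest. Of the 22 late inflammatory genes, 12 had a mean of at least 1 TPM. Acod1, which makes itaconate in activated macrophages (chromosome 14, 103046977 to 103056573), stood at 220 ± 127 TPM and the acute-phase gene Saa3 at 106 ± 45.7 TPM. Marco, Fpr2 and the anti-inflammatory cytokine gene Il10 followed at 18.4 ± 3.96, 9.59 ± 6.66 and 8.96 ± 4.71 TPM. F3 and Serpinb2 were lowest at 0.0767 ± 0.0862 and 0.103 ± 0.0231 TPM. Il6 and Il12b, chosen after their values were seen, had 0.493 ± 0.320 and 0.187 ± 0.138 TPM.

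The immediate early list, transcription factors and regulators that cells switch on within minutes of a signal, was led by Klf6 at 110 ± 34.3 TPM (chromosome 13, 5861482 to 5870394). The mRNA-destabilising factor gene Zfp36 had 107 ± 27.2, Junb 78.7 ± 15.4, Gadd45b 61.9 ± 21.1 and the phosphatase gene Dusp1 51.2 ± 12.6 TPM. Egr3 and Fosb were the lowest at 0.567 ± 0.384 and 1.04 ± 1.27 TPM. In total 21 of the 22 immediate early genes had a mean of at least 1 TPM.

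Early inflammatory genes lay above late inflammatory genes by 3.59 ± 0.22 on the log2(TPM + 1) scale, with 3.38, 3.82 and 3.56 in replicates 1, 2 and 3 (2-sided permutation of genes between the 30 and 22 members, p = 6e-05, adjusted p = 0.00012 over 4 contrasts). Early inflammatory and immediate early genes differed by 0.56 ± 0.36, which was not separable from chance (permutation p = 0.399, adjusted p = 0.399). That difference was 1.29 ± 0.14 in the read-based table (permutation p = 0.173) and 0.37 ± 0.78 on counts not scaled by length (permutation p = 0.806). The early minus late difference was 2.33 ± 0.14 among members of at least 1 TPM (permutation p = 0.00872). The contrasts with the interferon list were chosen after the levels were seen. The interferon median lay above the late inflammatory one by 6.08 ± 0.14 (permutation p = 5e-05, adjusted p = 0.00012) and above the early inflammatory one by 2.50 ± 0.22 (permutation p = 0.00014, adjusted p = 0.000187), in each of the 3 libraries. These p-values compare genes by their means over these libraries, not the printed mean differences themselves, and genes are not independent replicates. A sign flip over 3 libraries cannot give an exact p below 0.25.

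**Figure D1:**
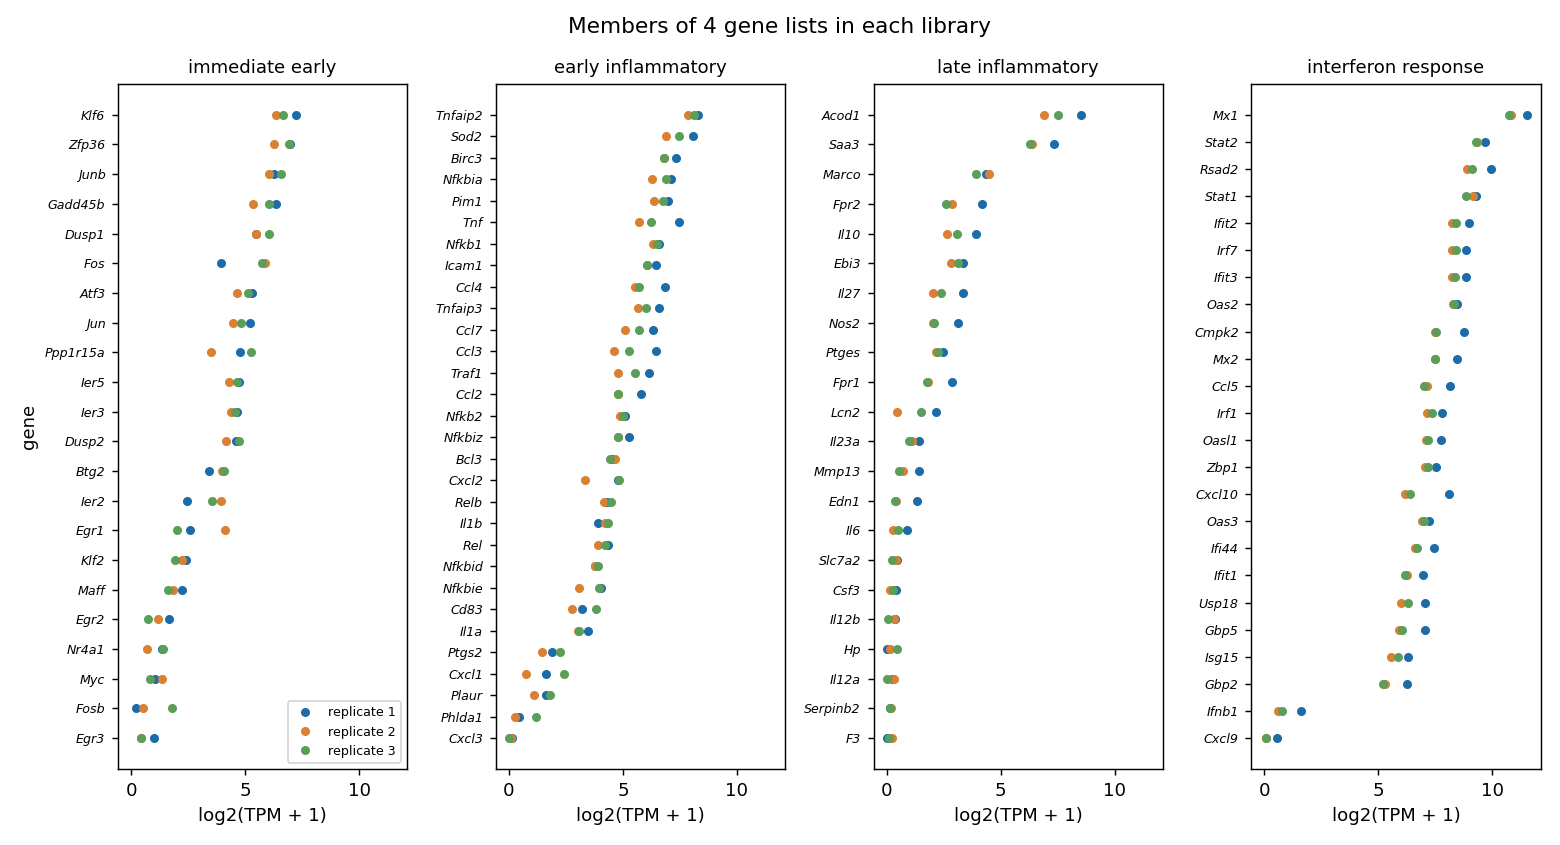
Level of each member of 4 gene lists in log2(TPM + 1) on the horizontal axis, with 1 point per replicate and genes ordered by their mean TPM. The interferon list reaches a median of 7.40, and the late inflammatory list has a median of 1.32.

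Macrophage genes were abundant, and markers of other cell types were low in the alignment-based table. The macrophage identity list had a median of 6.60 ± 0.11, led by Gpnmb, a lysosomal glycoprotein gene, at 1052 ± 238 TPM, the protease gene Ctsb at 466 ± 68.8 TPM and Adgre1, which encodes the macrophage antigen F4/80, at 330 ± 55.6 TPM. Cebpa was its lowest member at 3.80 ± 1.29 TPM. The medians of the neutrophil, dendritic, lymphocyte, stromal, erythroid and mast or basophil lists were 0.03 ± 0.04, 0.25 ± 0.04, 0.03 ± 0.03, 0.06 ± 0.07, 0.00 ± 0.00 and 0.00 ± 0.00. Only 2 of these 51 markers had a mean of at least 1 TPM, Cd4 at 9.30 ± 3.75 TPM and Zbtb46 at 1.58 ± 0.165 TPM. Of the 51, 16 had a mean of at least 1 TPM in the read-based table, where the medians of the 6 lists were, in the same order, 0.45 ± 0.01, 1.08 ± 0.18, 0.66 ± 0.10, 0.59 ± 0.17, 0.00 ± 0.00 and 0.02 ± 0.02. Chosen after their values were seen, Cd3d, Thy1 and Cxcr2 had 15.2 ± 2.43, 13.5 ± 1.56 and 4.61 ± 0.63 TPM there, and the tables were not tested for the cause of the difference. Col3a1 was listed at 0 TPM in replicate 1 and at 1.01 and 0.300 TPM in replicates 2 and 3.

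Genes of the TLR4 pathway had a median of 4.63 ± 0.12, with Tbk1, a kinase of the interferon arm, at 165 ± 20.2 TPM, Chuk at 97.2 ± 5.89, Irf3 at 85.1 ± 8.28 and the adaptor gene Tirap lowest at 3.44 ± 0.267 TPM. In the read-based table Tirap had 10.7 ± 1.09 TPM and was not the lowest. Negative regulators of the pathway had a median of 4.94 ± 0.13. Trafd1 led them at 560 ± 22.9 TPM, ahead of Trim30a at 250 ± 29.4 and the lipid phosphatase gene Inpp5d at 193 ± 15.2 TPM, while Sigirr was lowest at 0.550 ± 0.308 TPM.

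The remaining lists covered general cell functions. Housekeeping genes had a median of 5.24 ± 0.08, with the ferritin genes Fth1 at 871 ± 173 and Ftl1 at 339 ± 36.6 TPM, Actb at 418 ± 99.5 TPM and Pgk1 lowest at 5.79 ± 1.24 TPM. Ribosomal protein genes had a median of 4.45 ± 0.08, with Rpl10 at 134 ± 2.75 TPM and Rps16 at 3.79 ± 1.35 TPM as highest and lowest. In the read-based table Rps9 was highest at 122 ± 25.1 TPM, above Rpl10, and Rps16 stood at 10.5 ± 1.33 TPM. LXR targets had a median of 5.44 ± 0.29, led by the cholesterol exporter genes Abca1 (117 ± 20.0 TPM) and Abcg1 (93.0 ± 10.5 TPM), and cholesterol synthesis genes had a median of 3.56 ± 0.17. Stress and chaperone genes had a median of 3.94 ± 0.14, led by Hspa8 at 93.0 ± 11.6 TPM (by Ddit3 at 81.1 ± 20.7 TPM in the read-based table). Cell cycle genes had a median of 1.76 ± 0.23 (2.84 ± 0.24 in the read-based table), led by Pcna at 27.6 ± 7.63 TPM. Replication histones had a median of 2.39 ± 0.47, led by Hist2h2ac at 22.2 ± 7.15 TPM. Of the 23 lists, 14 lay above the 95th percentile of random protein-coding lists. The late inflammatory list lay at percentile 66.2, replication histones at 87.4 and cell cycle genes at 76.3. Among members and background genes of at least 1 TPM, the mitochondrial, cholesterol synthesis and stress lists no longer lay above the 95th percentile, at 94.6, 46.9 and 92.8, and the late inflammatory, replication histone and cell cycle lists lay at 6.41, at 1.67 and below 1. Against random lists matched on gene length, cholesterol synthesis lay at 94.0 and replication histones at 98.6.

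**Figure D2:**
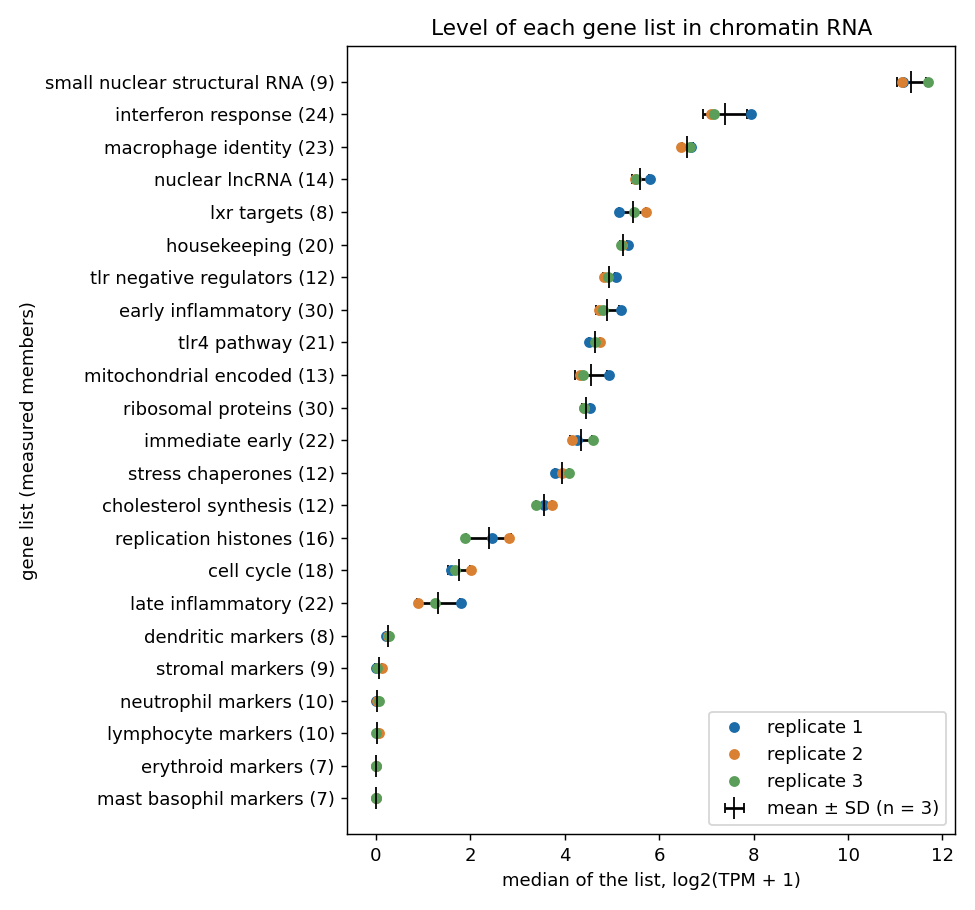
Median log2(TPM + 1) over all measured members of each of the 23 gene lists, with coloured points for the replicates and black bars for their mean ± SD (n = 3). The interferon list stands at 7.40 ± 0.47 and the markers of other cell types stand at 0.25 or lower.

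Nuclear RNAs took a large share of the libraries. Malat1 (ENSMUSG00000092341.3), a long noncoding RNA of nuclear speckles (chromosome 19, 5795690 to 5802672), held 10.8% ± 0.462 of all expected counts and 29613 ± 4104 TPM. Neat1, which builds paraspeckles, had 2335 ± 239 TPM, and Xist, the RNA that coats the inactive X chromosome, had 1119 ± 15.9 TPM. The nuclear long noncoding list had a median of 5.60 ± 0.18, and Meg3 was listed at 0 TPM in all 3 libraries (0.560 ± 0.13 TPM in the read-based table). Protein-coding genes held 65.0% ± 2.76 of the counts, with 67.7, 65.0 and 62.2% in replicates 1, 2 and 3. The neighbouring genes Gm26917, Gm42418 and CT010467.1 on chromosome 17, between 39843013 and 39848827, together held 15.2% ± 3.37, with 11.8, 15.2 and 18.5% in replicates 1, 2 and 3. CT010467.1 is annotated as ribosomal RNA and overlaps Gm42418 on the opposite strand, so the split of reads between them is uncertain. The rescaled TPM used below treats all 3 as ribosomal and leaves them out, along with features under 200 nt. How much of their share was ribosomal RNA left after depletion was not tested, so it should not be read as long noncoding RNA.

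Small structural RNAs were among the genes with the highest TPM in the alignment-based table. The list of small nuclear and structural RNAs had a median of 11.34 ± 0.31, with the ribozyme Rmrp at 67307 ± 19261, Rn7sk, which holds back transcription elongation, at 16110 ± 3975 and Rn7s1 at 7825 ± 1496 TPM. Rn7s1 and Rn7s2 had identical values in every library. The 10 highest genes also included the small nucleolar RNA genes Gm22988 (71354 ± 15356 TPM), Gm26447 (49742 ± 14875), Snord15b (29225 ± 2265), Gm25776 (14601 ± 1239) and Gm25835 (14418 ± 6062), the small nuclear RNA gene Gm22513 (14639 ± 5307) and Gm26917 (49488 ± 12051). The read-based table gave other values, with Gm26917 at 56080 ± 15448, the ribozyme Rmrp at 26214 ± 2903, Malat1 at 22731 ± 3442, Rn7sk at 7964 ± 2316, Gm22988 at 6999 ± 4031 and Gm26447 at 2511 ± 706 TPM. Features shorter than 200 nt took 39.2% ± 3.91 of TPM but 0.257% ± 0.102 of counts. Genes of the mitochondrial chromosome held 0.0370% ± 0.0140 of counts, with mt-Co1 at 182 ± 71.4, mt-Atp8 at 139 ± 32.7 (49.7 ± 16.1 in the read-based table) and mt-Nd6 at 49.8 ± 18.7 TPM (32.8 ± 13.7). Of the 13 protein-coding genes on it, mt-Co3 had the lowest mean at 0.150 ± 0.0794 TPM (32.4 ± 7.54 TPM in the read-based table), and 6 of the 13 had near-identical nuclear copies.

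Replicate 1 held more interferon and inflammatory RNA than the other two. All 22 detected interferon genes were highest in replicate 1, whereas 38.9% of all detected genes were. The interferon list lay 0.71 above the mean of replicates 2 and 3 (log2(TPM + 1), median of members), above all 10000 random lists matched on expression. The late inflammatory list lay 0.97 above, with 15 of 16 detected genes highest in replicate 1, and the early inflammatory list 0.40 above, with 19 of 29. Negative regulators of the TLR4 pathway lay 0.31 above, at percentile 98.8, with 9 of 11 highest in replicate 1. Mitochondrially encoded genes also lay higher in replicate 1, by 0.51, and lay lower in replicate 2, by 0.64, where 8 of 12 had their lowest value. Both medians include mt-Nd3, mt-Nd4l, mt-Co2 and mt-Atp6, each listed at 0 TPM in 2 libraries. Of the 4 detected stromal markers, 3 were lowest in replicate 1 and Acta2 was level at 0.830, 0.820 and 0.820 TPM. The median over the 4 lay lower in replicate 1 by 0.48 in TPM, 0.79 in rescaled TPM, 1.14 on thinned counts, 3.68 on TMM-scaled counts and 4.37 with DESeq2 size factors. These markers lay near the floor, with 1, 38 and 47 counts for Col1a1 and 0, 25 and 32 for Col3a1. The size of the difference thus depended on scale and pseudocount. In the read-based table Col1a1 had 1.19, 1.88 and 1.75 TPM and Col3a1 0, 0.65 and 0.27 TPM. The dendritic markers were not apart from random lists, at 0.22. Acod1 had 362, 117 and 181 TPM, and Mx1 had 2956, 1818 and 1670 TPM, in replicates 1, 2 and 3. Chosen after their values were seen, Cxcl10 had 268, 70.7 and 83.6 TPM and Tnf 177, 51.6 and 74.2 TPM.

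Other genes ran the other way or set another library apart. Chosen after their values were seen, Fos had 14.5, 57.6 and 52.2 TPM in replicates 1, 2 and 3, and Cd14, the co-receptor of TLR4, had 15.6, 27.1 and 60.9 TPM. The median deviation of immediate early genes in replicate 1 was 0.28, at percentile 99.9, in the same direction as the interferon list. Of the 22 genes, 11 were highest there and 5 lowest, but the median level of the list was 4.27, 4.15 and 4.60 in replicates 1, 2 and 3. All 14 detected replication histones were highest in replicate 2, by 0.76 in the median, with Hist1h1c at 12.0, 20.9 and 6.95 TPM. The histone list also lay 0.62 lower in replicate 3, where 11 of 14 had their lowest value. The early inflammatory list lay 0.54 lower in replicate 2, where 23 of 29 genes had their lowest value.

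**Figure D3:**
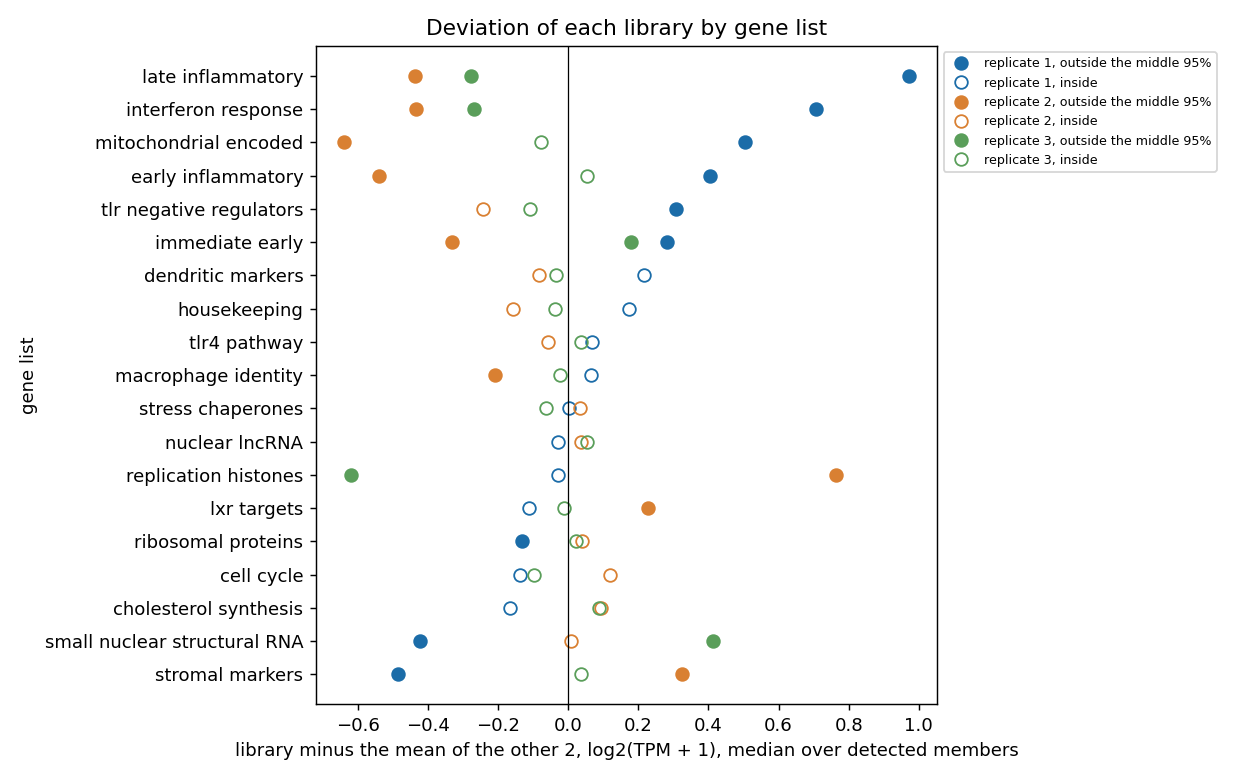
Median over detected members of each library minus the mean of the other two, in log2(TPM + 1), for the 19 lists with at least 3 detected members. Filled points lie outside the middle 95% of random lists matched on expression, and the interferon list of replicate 1 lies at 0.71.

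The spread between libraries was larger than that of like-expressed genes for 10 of 19 lists. It was largest for late inflammatory genes, with a median SD of 0.56 on the log2(TPM + 1) scale, followed by mitochondrially encoded genes at 0.55, replication histones at 0.53, interferon genes at 0.41, early inflammatory genes at 0.39 and immediate early genes at 0.36. The mitochondrial value includes mt-Nd3, mt-Nd4l, mt-Co2 and mt-Atp6, each listed at 0 TPM in 2 libraries while near-identical nuclear copies held counts. This order depended on the filter and scale. With members of a mean count of at least 1, the late inflammatory spread was 0.31, below those of mitochondrial genes, replication histones, interferon, early inflammatory and immediate early genes. The stromal spread, 0.29 in TPM, was the largest of all at 1.32 with a pseudocount of 0.1, 2.12 on TMM-scaled counts and 2.53 with DESeq2 size factors. Stromal markers had few counts, so the size of their spread cannot be read finely. Nuclear long noncoding RNAs (0.13), cholesterol synthesis genes (0.15) and TLR4 pathway genes (0.15) were not apart from random lists. The TLR4 pathway spread was 0.06 without replicate 1, at percentile 4.66. Without replicate 1, the interferon spread was 0.09, at percentile 30.4, the late inflammatory spread was 0.15, at percentile 82.3, and the stromal spread was 0.08, at percentile 31.5. The mitochondrial spread was 0.14 without replicate 2, at percentile 74.8. Without replicate 3 the macrophage spread was 0.19, at percentile 71.4, and that of small structural RNAs 0.20, at percentile 57.7. Small structural RNAs lay at 93.4 without replicate 1, and housekeeping genes at 82.5, 90.5 and 83.1 without replicates 1, 2 and 3. The immediate early, early inflammatory and replication histone lists stayed above the 95th percentile whichever replicate was left out. The early inflammatory spread itself fell to 0.25 without replicate 1. The biological coefficient of variation was 0.161 over 15879 genes in edgeR, between 0.123 without replicate 1 and 0.190 without replicate 3.

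The genes that differed most between libraries were mixed. Egr1, an immediate early transcription factor gene, had 5.01, 16.4 and 3.03 TPM in replicates 1, 2 and 3. The mitochondrial ribosomal RNA gene mt-Rnr1 had 66.3, 10.4 and 23.4 TPM. Snord22 was listed at 23178, 0 and 0 TPM with 477, 919 and 764 expected counts. The small nuclear RNA genes Gm26244 (21224, 113 and 23.7 TPM) and Gm24924 (2433, 113 and 23.7 TPM) shared their values in replicates 2 and 3. In the read-based table Snord22 had 1814, 2607 and 1762 TPM, Gm26244 had 2.53, 112 and 278 TPM and Gm24924 had 257, 360 and 278 TPM. B430305J03Rik had 0, 2.59 and 4.34 TPM but 0 in every library in the read-based table. The lincRNA gene Rmrp, which shares its symbol with the ribozyme gene, had 2089, 16205 and 8054 TPM. It spans chromosome 4 from 43492783 to 43493063 and contains the ribozyme gene (43492788 to 43493058) on the same strand. The split of reads between them is thus uncertain, and its values should not be read as those of a separate RNA. Gm10925, a nuclear copy of mt-Atp6, had 75.1, 0.790 and 48.6 TPM, and 1.54, 0 and 0 TPM in the read-based table. Gm5641 had 1.71, 7.40 and 10.9 TPM and Gm37110 had 1.06, 4.74 and 7.79 TPM, and neither showed this order in the read-based table.

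Transcripts annotated as retained introns were assigned a large part of the TPM of many genes. Chromatin RNA includes unspliced RNA, which was not told apart from retained introns here. Across 6584 genes with such a transcript and a protein-coding one, the median share was 46.8% ± 1.24. Ribosomal protein genes had a median share of 64.7% ± 1.51 (26 genes), early inflammatory genes 57.2% ± 3.71 (19), housekeeping genes 53.0% ± 3.10 (16), immediate early genes 46.5% ± 1.55 (6), interferon genes 43.3% ± 2.62 (16) and macrophage genes 33.4% ± 4.66 (9). Single genes, chosen after their values were seen, spanned nearly the whole range, from Dusp1 at 95.1% ± 0.358 and Cd83 at 93.6% ± 2.76 to Nfkbia at 8.13% ± 1.17 and Pim1 at 4.46% ± 2.24. Early inflammatory genes lay above housekeeping genes by 4.27 ± 3.10 percentage points (permutation p = 0.586, adjusted p = 0.856 over 11 lists) and immediate early genes differed by -6.45 ± 3.22 (permutation p = 0.606, adjusted p = 0.856), so neither list was separable from housekeeping genes. In the read-based table the early inflammatory difference had the opposite sign, at -2.62 ± 1.04 percentage points (permutation p = 0.654), and as a share of counts it was 17.6 ± 4.18 (permutation p = 0.255).

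The libraries resembled each other across genes. Of 55536 annotated genes, 15873 were detected at a mean expected count of at least 10, among them 11755 protein-coding genes. Pearson correlations across detected genes were 0.974 between replicates 1 and 2, 0.977 between 1 and 3, and 0.984 between 2 and 3, and Spearman correlations were 0.973, 0.977 and 0.981. All 3 were kept as separate samples, since the labels number them as biological replicates. The alignment-based and read-based tables correlated across detected genes at Spearman 0.898 to 0.904. Across transcripts with a mean count of at least 10, the lowest correlation was 0.796. All these correlations are across genes or transcripts, which are not independent replicates.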

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

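The tests on other cell types, on the starting amount and on copies of mitochondrial genes were chosen after the results were seen. Sequence of phage phiX174, a common sequencing control that no comparison used, took 1.24% of the expected counts in replicate 1 (exact 95% interval 1.23 to 1.24), 0.482% in replicate 2 (0.478 to 0.485) and 0.228% in replicate 3 (0.226 to 0.230). Features with a number in place of a gene identifier had 37, 24 and 37 counts in replicates 1, 2 and 3, on 5 such features in each library and 8 over all libraries.

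Interferon genes were higher in replicate 1 by 0.71 on the log2(TPM + 1) scale. Scaling of TPM by short and ribosomal RNAs was argued against, since the difference was 0.68 on TMM-scaled counts. It was 0.70 with all libraries thinned to 1 total. Random thinning hardly moves the ratios of genes with many counts, such as Mx1 with 51564, 42169 and 49920 in replicates 1, 2 and 3. Thinning could thus not decide on depth, which stays open. RNA carried by cells of the 6 other types examined was argued against as a direct source. No marker exceeded the mean of the other 2 libraries by more than 0.650 TPM (Clec9a) in replicate 1. The median excess of interferon genes was 73.9 TPM. The limits of this test were set after the values were seen, and an effect of such cells on the macrophages was not tested. Of the 51 markers, 16 had a mean of at least 1 TPM in the read-based table, against 2 in the alignment-based table, but the largest excess in the read-based table was 1.06 TPM (Cxcr2), against a median of 97.6 TPM for interferon genes. The amount of RNA at the start cannot be told apart from the replicate, because each amount had only 1 library. A difference between the cultures also stays open, and no biological explanation was tested because the design has 1 group.

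Mitochondrially encoded genes were listed at 0 in some libraries, such as mt-Atp6 with 0, 31.6 and 0 TPM, mt-Co2 with 0, 28.5 and 0 TPM, mt-Nd3 with 0, 19.0 and 0 TPM and mt-Nd4l with 25.7, 0 and 0 TPM in replicates 1, 2 and 3. In each library in which such a gene was at 0, all counts of the gene with its near-identical nuclear copies lay on the copies. These were 30 and 46 counts for mt-Nd3 in replicates 1 and 3, and 20 and 77 for mt-Nd4l in replicates 2 and 3. Whether those reads came from the mitochondrial genes was not tested. The smallest count of a gene with its copies, in a library in which the gene was listed at 0, was 20, for mt-Nd4l in replicate 2, below the limit of 100 set for this test. Such a total misses the limit wherever its reads were assigned, so no conclusion is drawn from the limit. With its copies mt-Atp6 had 440, 217 and 416 counts and mt-Co2 667, 364 and 487. Of the mt-Atp6 total, mt-Atp6 itself held 0, 212 and 0 counts and its copy Gm10925 held 440, 5.3 and 416. For mt-Atp6 the counts of replicates 1 and 3 were thus assigned to the copy, and mt-Co2 itself likewise held 0 counts in replicates 1 and 3. In the read-based table mt-Atp6 had 53.3, 21.3 and 32.6 TPM and mt-Co2 had 51.6, 34.2 and 0.05 TPM.

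Short RNAs differed more between libraries than longer ones in TPM, with a median SD of 0.33 for the 70 detected features under 200 nt and 0.16 for the rest. Division by effective lengths near 0 was argued against as the general cause: the median SD on counts scaled to library size was 1.28 times that on TPM. Counts of short RNAs can themselves depend on fragment length, so this ratio cannot exclude effective length as such. The effective length of Gm22988 was 5.34, 3.06 and 3.09 in replicates 1, 2 and 3. Of these 70 features, 3 had 0 TPM in a library with at least 10 counts, against none of the 15803 longer ones. The one with at least 100 counts was Snord22, with an effective length of 1.65 in replicate 1 and 0 in replicates 2 and 3, where its 919 and 764 counts became 0 TPM.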

How the results depend on the processing

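The rescaling of TPM, the thinning of counts and both interferon contrasts were chosen after seeing the data. All 4 list contrasts kept their sign and their side of 0.05 under every alternative run. The early minus late difference ranged from 2.33 to 4.26 over all alternatives. The numbers of detected genes, and of lists past each percentile over the 3 libraries together, stayed within 1.5 times of their values in all alternatives run. Within single libraries they moved more, as in replicate 3, where 5 lists lay outside the middle 95% and 8 did on thinned counts. The biological coefficient of variation was 0.0871 as the DESeq2 median of gene-wise dispersion and 0.123 to 0.190 when 1 replicate was left out. The protein-coding share was 31.6% of TPM against 65.0% of counts. The lowest correlation between libraries was 0.966 with a pseudocount of 0.1. The lowest Spearman correlation between the transcript tables was 0.456 over transcripts with 1 TPM in either table and 0.734 over all transcripts. The causes of these shifts were not tested. The retained intron difference of early inflammatory genes against housekeeping genes turned from 4.27 to -2.62 percentage points in the read-based table, and the cause was not tested. Of the list deviations outside the middle 95% of random lists, 3 changed sign on thinned counts: ribosomal proteins and small structural RNAs in replicate 1 to 0.009 and 0.053, and macrophage genes in replicate 2 to 0.002. Deviations inside it changed sign there too, such as nuclear long noncoding RNAs in replicate 1, from -0.03 to 0.03. The cause was not tested. Of the other values of single lists, 152 of level, 150 of spread and 211 of deviation kept their side of the percentile limit, 17 moved past it and 21 fell back. Too few members were left for a level of the neutrophil, stromal, erythroid and mast or basophil lists at 1 TPM or more, and for a spread of the dendritic and stromal lists at a mean count of at least 50. A retained intron share cannot be read finely for genes with few counts, and replicate 1 was the shallowest library at 14609979 counts.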

Other observations

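The families and single genes described here were chosen after their values were seen. The families were taken by symbol outside the fixed lists and not tested for enrichment. The 12 detected Ifi2 genes, DNA sensors and their relatives with Mndal counted among them, had a median of 6.68 ± 0.42 (log2(TPM + 1), SD, n = 3), with Mndal at 716 ± 184 TPM and Ifi213 at 528 ± 157 TPM. The 7 Schlafen genes had a median of 7.02 ± 0.31, with Slfn4 at 421 ± 197 TPM, and the 8 guanylate-binding protein genes 6.19 ± 0.44, with Gbp8 at 143 ± 31.9 TPM. The 12 Parp genes had a median of 6.06 ± 0.27, with Parp14 at 751 ± 134 TPM, and the 14 genes with symbols in H2-K, H2-D, H2-Q, H2-T or H2-M 5.90 ± 0.30, with H2-K1 at 1372 ± 225 TPM and H2-Ke6, whose symbol is also taken by H2-K, at 15.0 ± 4.35 TPM. The 45 Trim genes had a median of 3.53 ± 0.08. Oasl2 reached 602 ± 93.3 TPM. All 12 Ifi2 genes, all 7 Schlafen genes and all 5 Oas genes were highest in replicate 1, as were 7 of 8 guanylate-binding protein genes, 12 of 14 H2 genes and 8 of 12 Parp genes. Of the 45 Trim genes 18 were, near the share of 38.9% over all detected genes. The difference between families was not tested. Members of these families are similar in sequence, and reads shared between them were not tested for.

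Among 9955 genes with a mean count of at least 100, 72 lay over 1 log2 unit above the other libraries in replicate 1 and 14 lay below. In replicate 2 these numbers were 14 and 49, and in replicate 3 they were 14 and 19. On TMM-scaled counts they were 99 and 33, 22 and 56, and 19 and 27. Other protein-coding genes with high chromatin RNA were Rsrp1 at 1482 ± 82.9 TPM, the inhibitory receptor gene Lilrb4a at 1480 ± 445 TPM, the proton pump gene Tcirg1 at 1320 ± 117 TPM, the adaptor gene Fyb at 1131 ± 93.8 TPM and the kinase gene Ikbke at 1109 ± 89.1 TPM. Mir155hg, host of an inflammation-linked microRNA, had 51.8, 15.4 and 22.4 TPM in replicates 1, 2 and 3.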
